A study of Mus musculus with 12 samples.

How the data were processed

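Spleens of 12 mice were made into single-cell suspensions with lysis of erythrocytes, and libraries were made with the 10x Genomics 3' v2 kit, which counts the ends of transcripts with molecular identifiers, per the labels' protocols. Reads were processed with Cell Ranger 2.1.1 against mm10, per the submitters' processing notes. How cells were filtered, how doublets were treated, how cells were called CD4 or CD8a, and the annotation release were not given in the sources used here. The labels put 3 mice in each of 4 groups: wild type without stress, S100a9 knockout without stress, wild type after stress and knockout after stress.

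The authors deposited 8 tables, 4 for each cell type, of a signal that is the average expression of a gene per mouse, per the file headers. The values are linear, never negative and not whole, and the listed genes of a cell type sum to between 7367 and 8270 per mouse, under a scale of 10000. Each table holds all 12 mice and a set of genes that the authors selected for 1 comparison by a rule that was not given in the sources used here. A mouse's value for a gene was the same in every table of a cell type (0 genes differed), so the tables select genes from 1 set of averages per cell type. No fold change, p-value or number of cells accompanied the values, so the planned use of the authors' own statistics and the alternatives built on them were not run. The values are averages and not whole reads, so no count model was fitted and depth per mouse is unknown: no counting interval or detection limit can be given. No columns were left unused (0).

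Values were analysed as log2(value + 0.1) with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with a mean-variance trend), 3 mice against 3, over the genes the authors listed for that comparison. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Adjustment covered only genes that the authors had selected from these same mice, so this threshold need not hold false calls to the share it names. Fold changes are on the log2(value + 0.1) scale and understate the change of low genes. Errors of log2 changes are standard errors, and levels are given as mean ± SD over 3 mice. The difference of the stress effect between genotypes was an interaction term fitted to all 12 mice over every gene listed for a cell type, 2999 in CD4 and 2851 in CD8a cells. The difference between cell types was fitted to the CD8a minus CD4 log2 value within each mouse. A sum over a gene list was compared by a two-sided exact permutation test, which cannot go below p = 0.1 with 3 mice against 3.

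Gene lists, with markers of other cell types of the spleen among them, were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but 2. Lists with at least 5 listed members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. All genes were selected by the authors on these same mice, so counts over lists are not independent evidence of direction, and camera compares a list with other selected genes. No list was called in any of the 12 comparisons with an estimated correlation (0 lists). The rule named S100a9 and S100a8 wherever listed. It then took the 6 largest rises and 6 largest falls among called genes, with the mice of both groups fully separated, a mean at or above the table's median, and predicted genes and receptor segments left out. It last took the 2 smallest p from each list with at least 3 called members, up to 12 genes. Where fewer than 5 genes passed, the 5 smallest p were named as not passing. Other genes named as examples of a list, or among small counts, were chosen after their values were seen. Some genes that the rule named are not reported here.

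Gene positions and transcript lengths came from GENCODE M21, which is built on the same assembly as mm10. It matched 97.5% of the 2999 CD4 symbols and 97.6% of the 2851 CD8a symbols. Transcripts were aligned with Biostrings 2.70.1. The fits were tested on simulated data with the real means and residual spreads. Simulated noise was independent between genes, and genes were not selected on it. The authors' genes were selected on these mice, so the shares of false calls need not hold for the real calls. For CD4 stress in wild type (2413 genes, 200 changed), 73.7% of changes of 0.5 log2, 97.6% of changes of 1 and 99.7% of changes of 2 were recovered, with 4.42% false calls. For the CD4 interaction (2999 genes), 37.6% of changes of 0.5 and 88.8% of changes of 1 were recovered. For CD4 genotype under stress (87 genes, 17 changed), 51.7% of changes of 0.5 and 80.0% of changes of 1 were recovered.

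Alternatives were pseudocounts of 0.01 and 1, removal of the lowest 25% of genes by level, centring on each mouse's median, no mean-variance trend, sample quality weights, the mouse number as a block, all 4 groups in 1 fit, and leaving out each mouse. Fits without ribosomal protein genes, their pseudogenes and mitochondrially encoded genes were added after seeing the data, with the other genes scaled either to their own listed sum or to a common total of 10000 less the removed genes. The groups differ by mouse, so p-values of limma and of list sums measure the spread between animals.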

Results

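Repeated social defeat is a model of psychosocial stress in which mice are repeatedly defeated by an aggressor. Mice went through 10 days of the paradigm or stayed unstressed, followed by 1 day of behavioural testing, and splenocytes were collected on day 12. Single-cell RNA sequencing gave average expression per mouse in CD4 and in CD8a cells of 3 wild-type control, 3 S100a9 knockout control, 3 wild-type stressed and 3 knockout stressed mice. The design asks what stress changed in T cells, and whether loss of S100a9 altered it. S100a9 encodes a calcium-binding protein abundant in neutrophils and monocytes. Expression is given per 10000. On this scale the listed genes of CD4 cells summed to 7367 to 7562 in controls and 8120 to 8225 in stressed mice. In CD8a cells they summed to 7419 to 7615 and 8102 to 8270. If each mouse totals 10000, genes that were not listed had a smaller share after stress. The depth behind each average is unknown.

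S100a9 (chromosome 3, 90692632 to 90695721, minus strand, mm10) was measured at low levels in all 12 mice. In CD4 cells of wild-type mice it was 0.0110 ± 0.00613 (SD, n = 3) without stress and 0.0920 ± 0.0283 (SD, n = 3) after stress. In mice labelled knockout it was 0.0449 ± 0.00387 (SD, n = 3) without stress and 0.0251 ± 0.00378 (SD, n = 3) after stress. The CD8a values were 0.0175 ± 0.0150, 0.0703 ± 0.0290, 0.0363 ± 0.00848 and 0.0272 ± 0.0172 in the same order. Among controls, CD4 values were higher in all 3 mice labelled knockout than in all 3 wild-type mice, and CD8a values overlapped; the gene was not listed for this comparison and was not tested. Reads from the ends of transcripts can arise outside a deleted part, and the deleted part is not in the labels, so these values do not check the genotype labels. A second pair of genes did follow the labels. The mitochondrial gene mt-Nd3 (chromosome M, 9459 to 9806) made up at least 99.5% of the sum of mt-Nd3 and its nuclear copy Gm28438 (chromosome 1, 24612775 to 24613119, an unprocessed pseudogene) in every wild-type mouse, and at most 0.807% in every mouse labelled knockout, in both cell types.

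**Figure D1:**
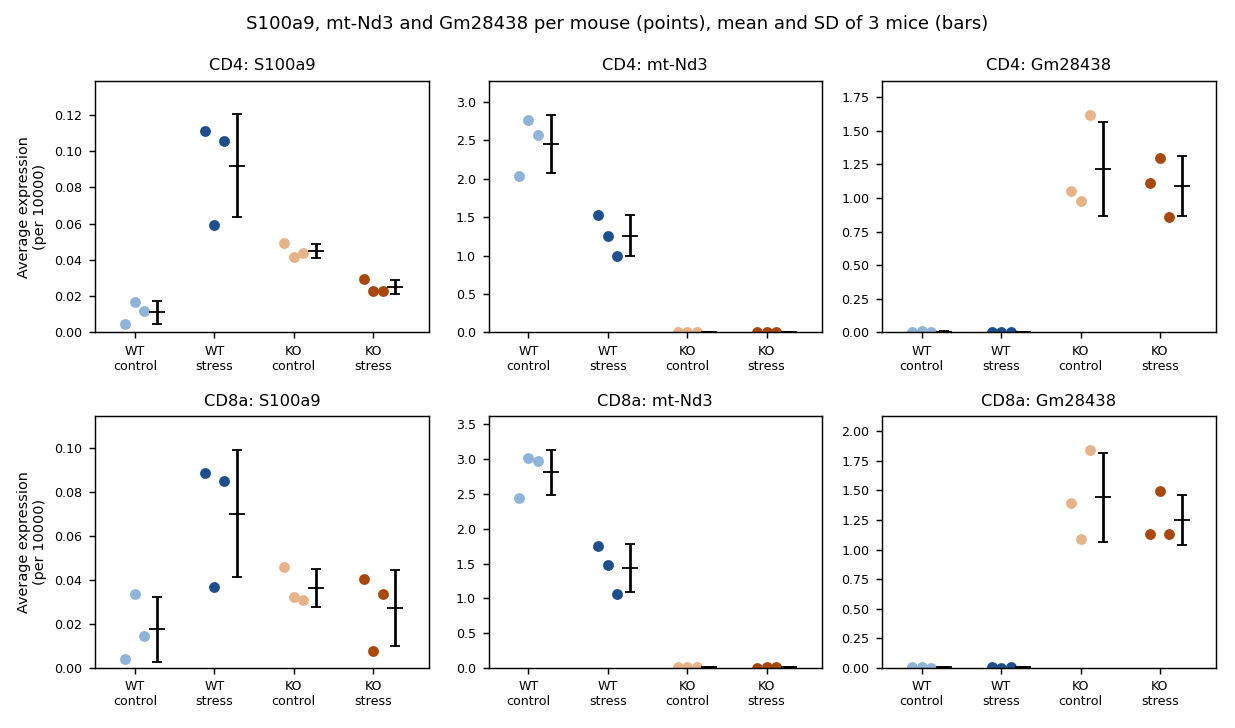
Average expression per 10000 of S100a9, mt-Nd3 and Gm28438 in CD4 (top) and CD8a cells (bottom), 1 point per mouse, with mean and SD of 3 mice as bars. S100a9 in CD4 cells averaged 0.0920 in stressed wild-type and 0.0251 in stressed knockout mice, and mt-Nd3 and Gm28438 exchanged places between the genotypes.

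In CD4 cells of wild-type mice, most listed effector genes were higher after stress. Gzma, the serine protease granzyme A, rose from 0.0709 ± 0.0625 to 1.83 ± 1.08 (SD, n = 3), and the chemokine Ccl5 from 2.51 ± 0.674 to 16.8 ± 8.42. Of the 27 listed activated, effector and memory genes, 20 rose and 0 fell (23 adjusted over the list alone). They included the calcium-binding S100a4 (log2 change 1.75 ± 0.29) and S100a6 (1.48 ± 0.29) and the galectin Lgals1 (1.13 ± 0.18). Camera called this list at an adjusted p of 0.00017, against an adjusted p = 0.42 with an estimated correlation. All 7 listed S100 genes rose, S100a9 by 0.78 ± 0.14 and S100a8, its partner in calprotectin, by 0.74 ± 0.17 (limma, adjusted p = 0.00029 and 0.0021). The S100 list had an adjusted p of 0.0054, and an adjusted p = 0.42 with an estimated correlation.

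Markers of other cells moved in the same mice. All 5 listed neutrophil markers rose, among them S100a9 and S100a8, which the S100 list also holds. The 7 neutrophil markers listed for any CD4 comparison summed to 0.240 in controls and 0.933 in stressed mice. Ly6c2, which is also in the effector list, made up 0.180 and 0.600 of these means. All 5 erythroid markers rose, such as Hba-a1 (1.31 ± 0.32). So did 4 of 6 monocyte and dendritic markers, such as Bst2 (0.72 ± 0.13) and Cst3 (0.48 ± 0.09), and 3 of 6 natural killer markers. The 3 that rose, Nkg7, Ccl5 and Gzma, also belong to the effector list, and none of these 4 lists passed camera (adjusted p 0.058 to 0.069). Cd4 itself fell (-0.64 ± 0.08), from 2.78 ± 0.218 to 1.75 ± 0.0956 (SD, n = 3). The T cell identity list that holds Cd4 did not fall as a sum. Its 13 genes summed to 71.8 ± 1.53 in controls and 75.2 ± 3.42 in stressed mice (SD, n = 3, exact permutation p = 0.3). Natural killer markers summed to 4.02 ± 0.956 in controls and 21.6 ± 10.5 in stressed mice (SD, n = 3), with 9.46 in stressed mouse 2 against 28.7 and 26.6 in the others. Ccl5 alone made up 2.51 of the control and 16.8 of the stressed mean. Interferon response genes rose in 10 of 14 cases and fell in 0 (camera adjusted p = 0.011, and adjusted p = 0.42 with an estimated correlation), and 9 of 12 class I antigen-processing genes rose.

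The same wild-type CD4 cells had more transcripts of ribosomal protein genes and of nuclear genes of oxidative phosphorylation. Of 82 cytosolic ribosomal protein genes 73 rose and 3 fell (74 and 3 adjusted over the list alone), led by Rpl24 (0.99 ± 0.08), and their sum went from 2289 ± 114 to 3009 ± 76.1 (SD, n = 3). Of 74 nuclear genes of oxidative phosphorylation 50 rose and 0 fell, and of 25 translation factors 17 rose and 2 fell. Camera gave adjusted p of 2e-13, 7.3e-07 and 0.0054, and an adjusted p = 0.39 with an estimated correlation for each. Antioxidant genes rose in 16 of 24 cases and fell in 1 (17 and 1 adjusted over the list alone; camera 0.0054, and adjusted p = 0.39 with an estimated correlation).

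Transcripts encoded by the mitochondrial genome fell. Of 11 mitochondrially encoded genes 8 fell and 0 rose, among them mt-Atp8 (-1.32 ± 0.11). The antisense RNA Kcnq1ot1 fell by 1.55 on the log2 scale, the largest fall under the rule, and Malat1, a nuclear RNA, went from 225 ± 10.2 to 154 ± 7.37 (SD, n = 3). Of 41 splicing genes, a list that holds Malat1 and Neat1, 21 fell and 8 rose, and 6 of those that rose encode Sm proteins, such as Snrpe and Snrpd2. Genes of T cell receptor and costimulation signalling fell in 11 of 15 cases and rose in 2, and naive and quiescent genes fell in 8 of 10 and rose in 1. Examples are the transcription factor Tcf7 (-0.75 ± 0.09) and Foxp1 (-0.82 ± 0.07). The adjusted p of these 4 lists was 0.00016, 0.0054, 0.00081 and 0.0014, and the adjusted p = 0.39 with an estimated correlation for each. Other large falls were the transcription factor Zbtb20 (-1.34 ± 0.13) and the histone methyltransferase Ash1l (-1.17 ± 0.11). Falls went with long transcripts: called protein-coding genes, ribosomal and mitochondrial ones left out, had a median length of 6409 bases where lower and 1240 where higher. The listed naive genes had a median of 4592 bases, receptor signalling genes 5082 and splicing genes 2403, against 875 for oxidative phosphorylation and 887 for ribosomal protein genes. Among other rising lists, S100 genes had a median of 519 bases and effector genes 1287.

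In total 748 genes were higher and 698 lower of 2413 listed (limma, adjusted p under 0.05). With centring on each mouse's median the split was 1015 higher and 697 lower. With the other transcripts rescaled to a common total after removal of ribosomal and mitochondrial genes it was 1090 and 686, and with scaling on the other listed genes after that removal 559 and 688. The listed genes were themselves unevenly placed, with 123 between -0.25 and 0 and 714 between 0 and 0.25.

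**Figure D2:**
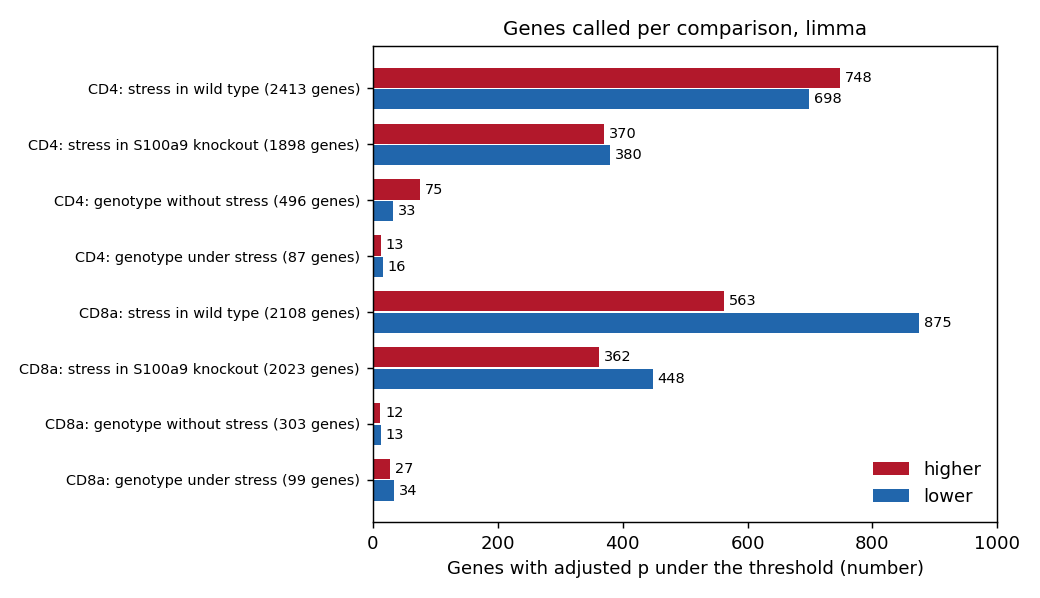
Number of genes called higher (red) or lower (blue) by limma in each of 8 comparisons, with the number of listed genes in brackets. The 4 stress comparisons had between 750 and 1446 called genes, and the 4 genotype comparisons between 25 and 108.

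In CD4 cells of knockout mice, stress again raised Gzma (2.83 ± 0.30), from 0.142 ± 0.0511 to 1.82 ± 1.26 (SD, n = 3). Natural killer markers, a list that holds Gzma and Ccl5, summed to 7.02 ± 2.04 in controls and 23.7 ± 14.9 in stressed mice, with 40.9 in stressed mouse 3 against 14.45 and 15.9 in the others. Ccl5 alone made up 4.77 of the control and 19.1 of the stressed mean. Ribosomal protein genes rose in 76 of 81 cases and fell in 0 (77 and 2 adjusted over the list alone), such as Rpl24 (0.84 ± 0.10) and Rps6 (0.77 ± 0.12). Camera gave this list 1.9e-24, and an adjusted p = 0.22 with an estimated correlation. Of 69 nuclear oxidative phosphorylation genes 34 rose and 0 fell (37 and 0 adjusted over the list alone; 5.9e-05, and adjusted p = 0.86 with an estimated correlation). All 8 listed mitochondrially encoded genes fell, with mt-Atp8 at -1.18 ± 0.08 (1.3e-06, and adjusted p = 0.24 with an estimated correlation). Splicing genes fell in 19 of 35 cases and rose in 5, with Prpf38b at -1.16 ± 0.09 (0.00056, and adjusted p = 0.62 with an estimated correlation). Of 11 receptor signalling genes 9 fell (2.6e-05, and adjusted p = 0.18 with an estimated correlation), and of 8 naive genes 6 fell and 1 rose, with Satb1 at -0.89 ± 0.08 (0.0071, and adjusted p = 0.62 with an estimated correlation).

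B cell and MHC class II markers fell in 10 of 11 cases in the same cells, including the immunoglobulin light chain Igkc (-1.02 ± 0.13) and the B cell scaffold Bank1 (-1.27 ± 0.17). Camera gave 2.6e-05, and an adjusted p = 0.62 with an estimated correlation. The sum of 12 such markers was 10.0 ± 2.47 in knockout control and 4.40 ± 0.480 in knockout stressed mice (SD, n = 3), and 6.75 ± 3.12 and 6.04 ± 1.72 in the wild type. Of 11 activated and effector genes 3 rose and 1 fell, the last being the interleukin 2 receptor chain Il2ra (-1.30 ± 0.16). Interferon genes fell in 6 of 13 cases and rose in 2. The sum of 36 interferon genes was 100.2, 71.3 and 63.4 in knockout control mice 1, 2 and 3. In stressed knockout mice it was 72.8, 61.3 and 67.0 (exact permutation p = 0.5). Of 7 chaperone genes 3 rose, with Hspa8 at 0.53 ± 0.11. S100a8 had a log2 change of 0.38 ± 0.18 that missed the threshold (limma, adjusted p = 0.12). Other large falls were Kcnq1ot1 (-1.51 ± 0.09), the large interferon-inducible Gvin3 (-1.17 ± 0.08) and the kinase Smg1 (-1.15 ± 0.10). Lower calls had a median transcript length of 6329 bases and higher calls 1129. In total 370 genes were higher and 380 lower of 1898 listed, and 162 and 372 after removal of ribosomal and mitochondrial genes and scaling on the other listed genes. Scaling the rest to a common total gave 663 and 361, and moved the median from 0.13 to 0.23.

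In CD8a cells of wild-type mice, stress raised Ccl5 from 8.34 ± 2.64 to 18.8 ± 2.62 (SD, n = 3; log2 change 1.20 ± 0.16). Activated and effector genes rose in 11 of 16 cases and fell in 1 (12 and 1 adjusted over the list alone; camera 0.0032, and adjusted p = 0.34 with an estimated correlation). The granule protein Nkg7 rose by 0.44 ± 0.09 and the surface antigen Ly6c2 by 0.46 ± 0.09. Of 6 listed S100 genes 5 rose (0.039, and adjusted p = 0.37 with an estimated correlation), with S100a9 at 0.53 ± 0.15 and S100a8 at 0.58 ± 0.19 (limma, adjusted p = 0.0082 and 0.015). Ribosomal protein genes rose in 75 of 83 cases and fell in 3 (6.7e-20), nuclear oxidative phosphorylation genes in 41 of 65 (2.2e-08) and translation factors in 19 of 26 with 4 falls (0.0019), each with an adjusted p = 0.34 with an estimated correlation. Chaperones rose in 6 of 9 cases (0.031, and adjusted p = 0.41 with an estimated correlation). The sum of 11 chaperone genes was 34.1, 33.8 and 48.8 in stressed mice 1, 2 and 3, against 27.5 to 32.4 in controls. Interferon genes rose in 6 of 10 cases and fell in 1 (0.041), antioxidant genes in 10 of 19 with 1 fall (0.0061) and natural killer markers in 3 of 5 (0.039), each with an adjusted p = 0.34 with an estimated correlation. The sum of 25 interferon genes, those listed for any CD8a comparison, did not rise. It was 41.72 ± 0.264 in controls and 41.55 ± 0.882 in stressed mice (SD, n = 3, exact permutation p = 0.8).

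Falls in these cells covered 10 of 11 mitochondrially encoded genes (11 adjusted over the list alone; 0.002), 27 of 40 splicing genes with 6 rises (27 and 8; 0.0078) and 13 of 16 receptor signalling genes (0.0021), each with an adjusted p = 0.34 with an estimated correlation. Naive genes fell in 7 of 9 cases, with Satb1 at -0.84 ± 0.09 and Foxp1 at -0.76 ± 0.09 (0.041, and adjusted p = 0.37 with an estimated correlation). T cell identity genes fell in 6 of 11 cases and rose in 2, with the transcription factor Bcl11b at -0.79 ± 0.11. Large single falls were Kcnq1ot1 (-1.41 ± 0.10), the dioxygenase Tet3 (-1.29 ± 0.12), the cytoskeletal linker Macf1 (-1.24 ± 0.13) and mt-Atp8 (-1.36 ± 0.11). The immunoglobulin heavy chain genes Ighd (-1.06 ± 0.17) and Ighm (-0.53 ± 0.11), B cell markers, also fell. Lower calls had a median transcript length of 6075 bases and higher calls 1224. In total 563 genes were higher and 875 lower of 2108 listed. Centring gave 1144 and 853, moving the median of all listed genes from 0.09 to 0.29, and scaling the rest to a common total gave 945 and 856.

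In CD8a cells of knockout mice, Ccl5 rose from 11.1 ± 3.26 to 26.7 ± 10.1 (SD, n = 3), and 9 of 14 activated and effector genes rose with 0 falls (camera 0.0092, and adjusted p = 0.59 with an estimated correlation). S100a6 rose by 0.76 ± 0.15. Translation factors rose in 15 of 24 cases and fell in 4 (16 and 4 adjusted over the list alone; 0.0498, and adjusted p = 0.75 with an estimated correlation). Ribosomal protein genes rose in 77 of 82 cases and fell in 3 (2.1e-21, and adjusted p = 0.27 with an estimated correlation), and 36 of 69 nuclear oxidative phosphorylation genes rose (40 adjusted over the list alone; 6.3e-06, and adjusted p = 0.62 with an estimated correlation). All 9 mitochondrially encoded genes fell (5e-06, and adjusted p = 0.27 with an estimated correlation), as did all 10 naive genes (9.9e-06, and adjusted p = 0.085 with an estimated correlation) and 10 of 11 receptor signalling genes (1.5e-06, and adjusted p = 0.095 with an estimated correlation). Splicing genes fell in 25 of 40 cases and rose in 5 (9.9e-06, and adjusted p = 0.085 with an estimated correlation). B cell and class II markers fell in 12 of 13 cases, with H2-Ab1 at -1.46 ± 0.14 and Cd74 at -1.35 ± 0.16 (1.6e-06, and adjusted p = 0.42 with an estimated correlation), and T cell identity genes in 8 of 11, with 1 rise (8 and 2 adjusted over the list alone; 0.015, and adjusted p = 0.60 with an estimated correlation). Interferon genes fell in 5 of 11 cases and rose in 1. The sum of 25 interferon genes was 63.5, 47.6 and 46.4 in knockout control mice 1, 2 and 3. In stressed knockout mice it was 47.2, 43.2 and 44.6 (exact permutation p = 0.2). Lower calls had a median transcript length of 5987 bases and higher calls 1053. In total 362 genes were higher and 448 lower of 2023, 175 and 435 with scaling on the other listed genes after that removal, and 650 and 421 with the rest scaled to a common total, which moved the median from 0.11 to 0.22.

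**Figure D3:**
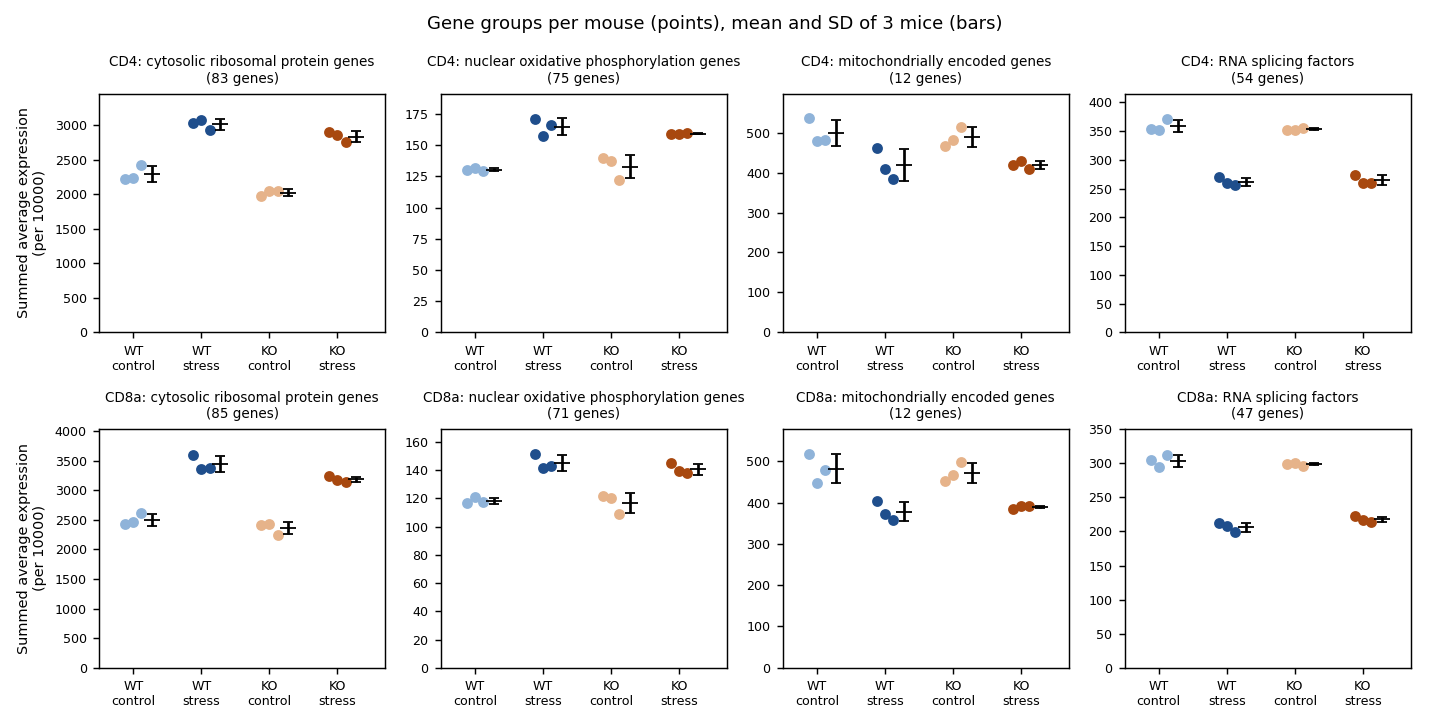
Summed average expression per 10000 of 4 gene groups in CD4 (top) and CD8a cells (bottom), 1 point per mouse, with mean and SD of 3 mice as bars. Ribosomal protein genes in CD4 cells averaged 2289 in wild-type control and 3009 in wild-type stressed mice, and splicing genes 359 and 262. The splicing list holds the noncoding RNAs Malat1 and Neat1, and Malat1 made up most of its sum in both of these groups.

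The stress effects in the 2 genotypes come from different mice and can be set side by side. Of 1471 genes listed in CD4 cells for both, 92.5% changed in the same direction, 290 were called higher in both (146 if the lists were independent), 293 lower in both (59.0) and 0 in opposite directions. In CD8a cells the values were 1382 genes, 94.3%, 275 higher (121), 370 lower (99.3) and 0 opposite. Pearson's r across genes was 0.94 in CD4 and 0.96 in CD8a cells. Genes are not independent replicates, and being listed for both comparisons raises these shares. Libraries 1 to 6 are the controls and 7 to 12 the stressed mice of both genotypes. A library batch would therefore also give such agreement.

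**Figure D4:**
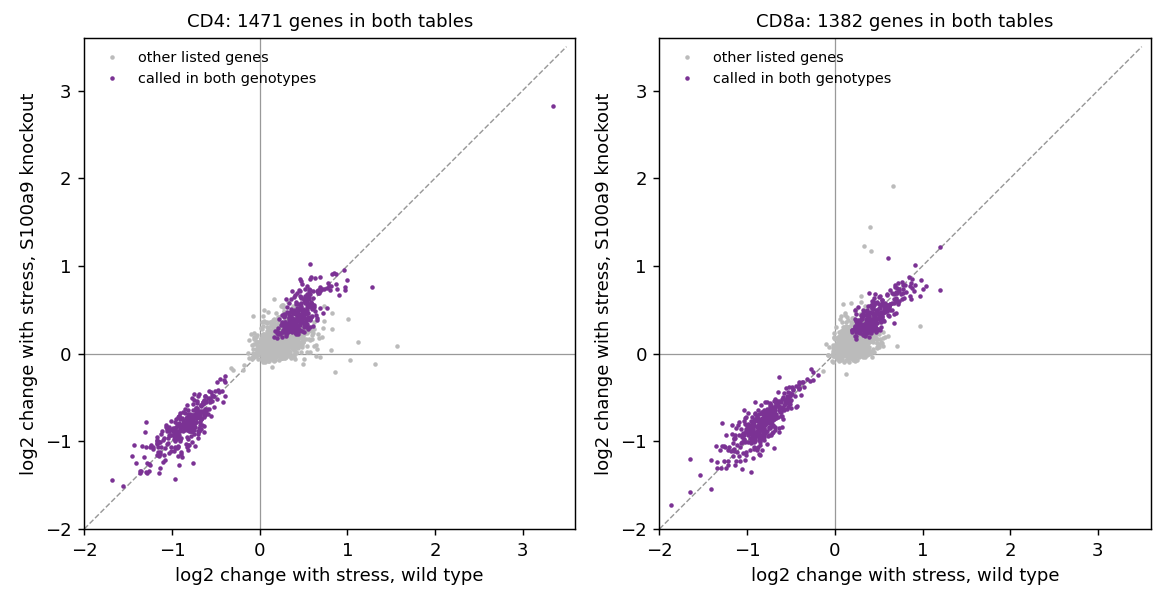
Log2 change with stress in wild-type (horizontal) against knockout mice (vertical) for genes listed in both tables, in CD4 (left) and CD8a cells (right), with genes called in both genotypes in purple and a dashed line of equality. Called genes lay in the upper right or lower left, with 0 in opposite directions.

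Whether knockout altered the response to stress was tested with the interaction. Limma called 0 of 2999 genes in CD4 and 0 of 2851 in CD8a cells, where 284 and 204 had an unadjusted p under 0.05. The smallest p in CD4 cells belonged to S100a9 itself (-0.99 ± 0.17, adjusted p = 0.069) and the membrane protein Tmem176b (-1.42 ± 0.25, adjusted p = 0.069), neither past the threshold. Next came Tmem176a (-1.29 ± 0.28), Jaml (-0.98 ± 0.21) and the B cell kinase Blk (-0.94 ± 0.20), at an adjusted p of 0.19. S100a9 was higher in all 3 stressed than in all 3 control wild-type mice and lower in all 3 stressed than in all 3 control knockout mice. Without knockout control mouse 3 the CD4 count was 17, and without wild-type stressed mouse 2 it was 2. In CD8a cells the smallest p was for Coro2a (-1.18 ± 0.22, adjusted p = 0.13), and S100a9 had -0.63 ± 0.20 (adjusted p = 0.62). Camera called 12 lists in CD4 and 4 in CD8a cells and 0 with an estimated correlation. In CD4 cells 33 effector genes had a median difference of -0.59 (2.6e-06, and adjusted p = 0.56 with an estimated correlation) and 7 S100 genes -0.77 (8.8e-05, and adjusted p = 0.49 with an estimated correlation). After stress the effector genes summed to 54.9 ± 18.0 in the wild type and 59.25 ± 20.9 in the knockout (SD, n = 3, exact permutation p = 0.8). In controls they summed to 25.02 ± 3.87 and 45.2 ± 12.9 (exact permutation p = 0.1, the smallest possible), with 57.7, 45.9 and 31.95 in knockout control mice 1, 2 and 3. The S100 genes summed to 17.63 and 18.85 after stress (exact permutation p = 0.8). In controls they summed to 8.896 and 18.63 (exact permutation p = 0.1), with 24.28, 21.28 and 10.33 in knockout control mice 1, 2 and 3. The 12 B cell markers had -0.94 (2.6e-06, and adjusted p = 0.49 with an estimated correlation), and 36 interferon genes -0.35 (2e-05, and adjusted p = 0.64 with an estimated correlation). The interferon sum was 100.2 in knockout control mouse 1 against 71.3 and 63.4 in mice 2 and 3.

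Between cell types, the stress change in the wild type was lower in CD8a than in CD4 cells for 6 of 1627 genes, and higher for 0. They were Ccl5 (-1.36 ± 0.22, adjusted p = 0.0083), S100a6 (-0.79 ± 0.14), Lgals1 (-0.74 ± 0.11), S100a11 (-0.64 ± 0.11), the respiratory chain gene Cox5b (-0.39 ± 0.08) and S100a10 (-0.35 ± 0.07). S100a9 itself had -0.25 ± 0.15 and S100a8 -0.16 ± 0.16, neither past the threshold (limma, adjusted p = 0.75 and 0.83). The count was 0 without the mean-variance trend, without stressed mouse 3 or without control mouse 2, and was 3 without stressed mouse 1, 27 without stressed mouse 2 and 1 without control mouse 3. In the knockout 0 of 1452 genes passed (limma, 48 at an unadjusted p under 0.05). The smallest p there was for the haemoglobin gene Hbb-bs (1.83 ± 0.34, adjusted p = 0.11), followed by Hba-a1 (1.34 ± 0.34), the chaperone gene Dnaja1 (-0.31 ± 0.08), Hbb-bt (1.52 ± 0.40) and Hba-a2 (1.38 ± 0.37), at an adjusted p of 0.59. The count was 1 without stressed mouse 1 and 4 without stressed mouse 2.

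Without stress, CD4 cells of mice labelled knockout differed from the wild type in 75 higher and 33 lower of 496 listed genes, with p-values adjusted over these selected genes alone. S100a4 was higher (0.569 ± 0.226 against 3.20 ± 1.87, SD, n = 3; log2 difference 2.11 ± 0.51), as were S100a11 (0.88 ± 0.22), Ccr6, a chemokine receptor of Th17 cells (1.12 ± 0.22), and Tmem176a (1.09 ± 0.20). Th17 and type 3 genes were higher in 4 of 8 cases (5 adjusted over the list alone), effector genes in 6 of 18 (9) and interferon genes in 6 of 31 with 1 lower, Ifi208 (-0.61 ± 0.13). These 3 lists did not pass camera (adjusted p 0.059 to 0.081). Markers of other cells were higher in the same mice, with all 4 listed haemoglobin genes, such as Hbb-bs (3.02 ± 0.67), and 4 of 9 monocyte markers (9 adjusted over the list alone), such as Lyz2 (1.19 ± 0.29) and Fcer1g (0.88 ± 0.22). Ribosomal protein genes were lower in 19 of 52 cases (29 adjusted over the list alone), with Rpl38 at -0.69 ± 0.10 and Rps29 at -0.56 ± 0.12, which camera called at 1.8e-30, and an adjusted p = 0.33 with an estimated correlation. Of 4 glucocorticoid-responsive genes 2 were lower, Tsc22d3 (-0.55 ± 0.14) and the receptor Cxcr4 (-0.80 ± 0.23).

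The count of 108 was 2 without knockout control mouse 1 or 2 or wild-type control mouse 2, 3 without wild-type control mouse 3, 27 without wild-type control mouse 1 and 252 without knockout control mouse 3. Over these 6 fits the median difference of the listed genes was 0.15 to 0.25, against 0.20 with all mice, and 162 to 316 genes had an unadjusted p under 0.05, against 279. Interferon genes summed to 100.2, 71.3 and 63.4 in knockout control mice 1, 2 and 3, against 56.0 to 56.6 in the wild type, and erythroid markers to 6.65, 5.11 and 1.52 against 0.847 to 1.05. Centring on each mouse's median gave 26 higher and 104 lower genes, and moved the median difference from 0.20 to -0.04.

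After stress, CD4 cells of mice labelled knockout had 13 higher and 16 lower of 87 genes. Of the 29 called genes 11 differed by over 1.5-fold, among them mt-Nd3 (-3.72 ± 0.19), Gm28438 (3.51 ± 0.19), Ifi208 (-0.77 ± 0.15) and Rell1 (-0.60 ± 0.17). Higher genes included Ifi27l2a (0.45 ± 0.13), Lars2 (0.27 ± 0.08) and mt-Cytb (0.19 ± 0.03), and lower ones the noncoding RNA Gas5 (-0.31 ± 0.08) and 9 of 31 ribosomal protein genes, such as Rpl39 (-0.27 ± 0.06; camera 5.9e-09, and adjusted p = 0.19 with an estimated correlation). The neutrophil granule genes Ngp (0.79 ± 0.22) and Lcn2 (0.73 ± 0.19) were higher. Centring gave 7 higher and 2 lower genes, 5 of them among the 29, and moved the median from -0.11 to 0.00. Removal of ribosomal and mitochondrial genes gave 4 and 2, or 7 and 5 with the rest scaled to a common total. The count was 2 without any of wild-type stressed mouse 1 or 2 or knockout stressed mouse 2 or 3, 8 without knockout stressed mouse 1 and 52 without wild-type stressed mouse 3.

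In CD8a cells without stress, 12 genes were higher and 13 lower of 303 in mice labelled knockout. The membrane protein gene Ms4a4b was higher (16.5 ± 0.327 against 19.6 ± 0.370, SD, n = 3), and Dapl1 lower (-0.34 ± 0.06). Rpl38 (-0.64 ± 0.13), Rps29 (-0.46 ± 0.10) and Rpl35 (-0.39 ± 0.07) were the 3 lower of 46 ribosomal protein genes (camera 0.00063, and adjusted p = 0.50 with an estimated correlation). None of 18 interferon genes passed (limma; median 0.52; camera 0.012, and adjusted p = 0.50 with an estimated correlation). Centring gave 7 higher and 123 lower genes, and moved the median from 0.09 to -0.11. The count of 25 was 10 without knockout control mouse 2, 9 without wild-type control mouse 2, 14 without wild-type control mouse 3 and 47 without wild-type control mouse 1.

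After stress, CD8a cells of mice labelled knockout had 27 higher and 34 lower of 99 genes. Of 36 ribosomal protein genes 22 were lower, such as Rpl36 (-0.26 ± 0.06) and Rplp1 (-0.14 ± 0.02; camera 1.6e-09, and adjusted p = 0.38 with an estimated correlation), but with centring Rpl39, Rpl37, Rps21, Rpl36a, Rplp1 and Fau turned positive and 2 genes were lower against 39 higher, 29 of these 41 among the 61, with the median moved from -0.13 to 0.14. Removal of ribosomal and mitochondrial genes gave 19 higher and 11 lower genes, or 21 and 12 with the rest scaled to a common total. Gas5 was lower (-0.41 ± 0.08) and Ms4a4b higher (0.22 ± 0.06). Erythroid genes were higher in 4 of 5 cases, with Hbb-bs at 3.09 ± 0.74 (camera 0.028, and adjusted p = 0.61 with an estimated correlation), and so were all 3 listed neutrophil genes, Ngp (0.61 ± 0.10), Camp (0.43 ± 0.10) and Lcn2 (0.41 ± 0.12). Erythroid markers summed to 16.97, 2.24 and 6.58 in stressed knockout mice 1, 2 and 3 and to 1.07 to 1.53 in stressed wild-type mice. The count of 61 was 3 without knockout stressed mouse 3, 12 without wild-type stressed mouse 2, 15 without knockout stressed mouse 1 and 40 without knockout stressed mouse 2.

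The genotype effects without and under stress also come from different mice. Of 64 genes listed for both in CD4 cells, 3 were called higher in both (1.56 if independent), 8 lower in both (4.69) and 0 in opposite directions. Of 58 in CD8a cells, 6 were higher in both (1.345 if independent), 2 lower in both (2.07) and 0 opposite. Besides mt-Nd3 and Gm28438, the genes Rell1 and Rab4a were called in both cell types with and without stress. In CD8a cells Rab4a was higher by 0.91 ± 0.07 without and 0.90 ± 0.12 under stress, and Rell1 differed by -1.02 ± 0.11 and -0.59 ± 0.15.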

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

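The tests of exchanged mice and of free RNA were chosen only after the S100a9 values were seen.

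S100a9 in CD4 cells was singled out because its stress effect differed between genotypes by -0.993 on the log2 scale (interaction, limma, adjusted p = 0.0686, short of the threshold). It was higher in 3 of 3 stressed wild-type mice than in any wild-type control, and lower in 3 of 3 stressed mice labelled knockout than in any knockout control. The tables argue against single mice exchanged between the genotypes, since 0 libraries had the mt-Nd3 to Gm28438 balance of the other genotype, but that balance is known only from the labels, so an exchange of all labels stays open. Free RNA from other cells stays open as a source in mice labelled knockout. The mean log2 difference of S100a9 between CD4 and CD8a cells was 0.15 (95% interval -0.365 to 0.666, exact sign-flip p = 0.5, n = 6). That interval is too wide to call the levels alike. If the labels hold, other cells of such a mouse carry the same targeted allele. Their free RNA would then also need a transcript kept by that allele, so like levels could not tell these sources apart. A transcript kept by the targeted allele also stays open, with no read sequence available: the ratio of S100a9 to S100a8 in stressed mice labelled knockout and stressed wild-type mice was 0.28 (mice 0.237 to 0.321) and 1.01 (0.736 to 1.51) in CD4 and 0.546 (0.229 to 0.785) and 1.1 (0.703 to 2.27) in CD8a cells, and in controls 0.923 (0.555 to 5.12) and 0.935 (0.614 to 1.51) in CD4 and 0.897 (0.572 to 2.87) and 2.75 (2.05 to 4.35) in CD8a cells.

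The other 6 genes had a stress effect in wild-type mice that differed between CD8a and CD4 cells of the same mice (limma). The log2 differences were -1.36 for Ccl5 (adjusted p = 0.00832), -0.786 for S100a6 (adjusted p = 0.0151), -0.745 for Lgals1 (adjusted p = 0.00572), -0.639 for S100a11 (adjusted p = 0.0107), -0.389 for Cox5b (adjusted p = 0.0434) and -0.355 for S100a10 (adjusted p = 0.0353). This count of 6 was 0 without stressed mouse 3 or control mouse 2, 1 without control mouse 3, 3 without stressed mouse 1 and 27 without stressed mouse 2.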

How the results depend on the processing

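Fits without ribosomal and mitochondrial genes were chosen only after the results were seen. Counts for the 4 stress comparisons stayed within 1.5 times in every fit run, with leave-one-out ranges of 1255 to 1423 (CD4, wild type), 625 to 810 (CD4, knockout), 1331 to 1370 (CD8a, wild type) and 700 to 805 (CD8a, knockout). The share of genes changed alike in both genotypes went from 92.5% to 91.9% in CD4 and from 94.3% to 94.2% in CD8a cells without the lowest genes. Genotype counts moved, and the cause was not tested except where genes or mice were removed. CD4 without stress (108) had 4 with pseudocount 1, 4 without the lowest genes, 69 without a trend, 267 with weights, 227 with all 4 groups, 12 and 19 without ribosomal and mitochondrial genes (listed sum, common total), and 2 to 252 leaving out 1 mouse. CD4 under stress (29) had 17 with pseudocount 1, 9 centred, 55 with weights, 6 and 12 without ribosomal and mitochondrial genes, and 2 to 52 leaving out 1 mouse. CD8a without stress (25) had 12 without the lowest genes, 130 centred, 63 without a trend, 62 with weights, 104 with all 4 groups, 10 without ribosomal and mitochondrial genes (listed sum), and 9 to 47 leaving out 1 mouse. CD8a under stress (61) had 37 without the lowest genes, 30 and 33 without ribosomal and mitochondrial genes, and 3 to 61 leaving out 1 mouse. The interaction (0 by limma, 284 and 204 at an unadjusted p under 0.05) had 1 in CD4 cells with pseudocount 0.01, 1 without a trend and 0 to 17 leaving out 1 mouse, and 0 to 1 in CD8a cells. The CD8a to CD4 difference had 0 without a trend and 0 to 27 leaving out 1 mouse in the wild type (6), and 1 with weights and 0 to 4 in the knockout (0 by limma, 48 unadjusted). Mouse numbers did not pair samples (correlations -0.24 to 0.24, 3 of 24 over 0.1), and as a block they gave 229 (CD4) and 13 (CD8a) for genotype without stress, 1 for the CD8a interaction, and 16 and 6 for the CD8a to CD4 difference in wild type and knockout. Gene lists past camera fell to 0 in all 12 comparisons with an estimated correlation. With centring they went from 1 to 6 for CD4 genotype without stress, from 1 to 0 under stress, and from 2 to 1 for CD8a genotype under stress. Centring reversed 6 genes in CD8a genotype under stress: Rpl39 (0.011), Rpl37 (0.014), Rps21 (0.033), Rpl36a (0.041), Rplp1 (0.13) and Fau (0.12). Of 2667 fits of 171 named-gene results, 2256 kept direction and side of the threshold, 383 were weaker, 22 stronger and 6 reversed. DESeq2 was not run, since the values are not counts. The authors' own p-values were not used, since none accompanied the values. Depth is unknown, so its limits cannot be given.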

Other observations

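The tests of composition, of a library batch, of reads shared alike in both genotypes, of lower mitochondrial transcription, and of length in mitochondrial genes were chosen only after the results were seen.

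In CD8a cells without stress, interferon genes summed to 63.5, 47.6 and 46.4 in the 3 knockout mice and to 41.6 to 42.0 in the wild type. B cell and class II markers in CD8a cells summed to 10.2 ± 3.47 in wild-type control, 6.22 ± 1.27 in wild-type stressed, 13.1 ± 2.06 in knockout control and 6.32 ± 0.600 in knockout stressed mice (SD, n = 3). Natural killer markers in CD8a cells went from 16.2 ± 3.17 to 29.3 ± 2.95 in the wild type and from 19.9 ± 2.84 to 37.9 ± 11.2 in the knockout. Ccl5 alone made up 8.34 and 18.8 of the wild-type means and 11.1 and 26.7 of the knockout means.

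In all 4 stress comparisons ribosomal protein transcripts were higher and long and mitochondrial transcripts lower. The tables argue against a larger ribosomal share pushing other genes down as the whole cause. The log2 shift of the rest was -0.14 to -0.19, where 377 to 871 listed genes per comparison lay at or below -0.25. At least 96.6% of lower calls stayed lower once ribosomal and mitochondrial genes were taken out and the rest scaled to a common total. Few listed genes lay between -0.25 and 0 (42 to 173), so the authors' selection by itself favours a high share. A bias by transcript length between control and stressed libraries may account for the nuclear genes. The falling naive, receptor signalling and splicing lists and the rising S100, effector and oxidative phosphorylation lists were not tested apart from length. Spearman's rho of change with length across protein-coding genes was -0.676 and -0.600 in CD4 and -0.758 and -0.616 in CD8a cells, wild type and knockout (permutation p = 1e-04, the smallest 10000 permutations can give). Lengths were shuffled among genes, which are not independent, so this p does not measure the spread between mice. Over the 4 comparisons rho was -0.103 to -0.161 within higher calls and -0.3 to -0.442 within lower calls. Selecting genes by their change can itself weaken rho. The tables argue against such a bias for mitochondrial genes, which are short and had median log2 changes of -0.89 to -1.01, where nuclear genes no longer than these had medians of 0.157 to 0.268. Stress, RNA quality and a library batch cannot be told apart, as 0 of 12 libraries depart from numbers 1 to 6 for control and 7 to 12 for stressed mice.

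The balance of mt-Nd3 and Gm28438 was exchanged between genotypes in all 12 mice. The tables argue against lower mitochondrial transcription in mice labelled knockout, as the other mitochondrially encoded genes had median log2 differences of at least 0.0795. The reference transcripts are 100% identical over 342 aligned bases (348 and 345 long), so reads may be shared between the gene and its nuclear copy, but the tables argue against sharing alike in both genotypes, as the share of mt-Nd3 lay at least 98.7 percentage points apart. A mitochondrial sequence variant carried by the knockout line, which could move reads from the gene to its copy, cannot be told apart from other sources. No read sequence is available. The alignment was local and can leave out differing ends, so its 0 differing bases hold for the aligned stretch only. The sum of both genes in the wild type and in mice labelled knockout was 2.46 and 1.22 in CD4 controls, 2.81 and 1.45 in CD8a controls, and 1.26 and 1.09 in CD4 and 1.44 and 1.26 in CD8a cells after stress.

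Sequence linked to the S100a9 locus was tested as a hypothesis for the genotype calls. Of 154 called genes 6 lay within 10 Mb (Rps27, S100a11, S100a6, S100a4, Gm19739 and Anp32e) against 2.87 expected (Fisher's exact p = 0.0652). The expected number was taken over 3596 genes listed for any comparison, stress included. Only genes listed for a genotype comparison could be called, so this test cannot decide and linkage stays open.

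Other splits of the same mice were fitted over genes that the authors had selected for the real groups, which by itself lowers the counts of the other splits in the comparisons of 2 groups. With 3 mice against 3 there are 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each of the 8 comparisons of 2 groups. Real and highest other counts in CD4 cells were 1446 and 0 for stress in the wild type, 750 and 0 in the knockout, 108 and 0 for genotype without stress and 29 and 2 under stress. In CD8a cells they were 1438 and 0, 810 and 0, 25 and 1, and 61 and 0. For CD8a against CD4 they were 6 and 1 in the wild type (1 of 10 splits) and 0 and 5 in the knockout (10 of 10 splits; limma, 48 at an unadjusted p under 0.05). For the interaction, 100 of 100 splits gave as many genes as the real 0 in both cell types (limma, 284 and 204 unadjusted), which any split does, so these counts say nothing about chance. Of the other splits 5 in CD4 and 8 in CD8a cells had any call, with highest counts of 57 and 18, which may point to a structure of the mice that was not tested.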
